A study of Saccharomyces cerevisiae with 5 samples.

How the data were processed

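Total RNA of 5 Saccharomyces cerevisiae cultures was put on a human Affymetrix array, the U133 Plus 2.0, which carries 54675 probe sets. Per the labels, the RNA was extracted with hot acidic phenol, 5 micrograms per sample were reverse transcribed from an oligo-dT primer with a T7 promoter, and biotin-labelled antisense RNA was transcribed in vitro. The strain was BY4742, a laboratory strain, or its isogenic cnb1 knockout. CNB1 encodes the regulatory subunit of calcineurin, a calcium-dependent phosphatase. There were 5 groups of 1 array each. These were untreated yeast, carvacrol at 0.005 percent for 15 min, carvacrol at 0.01 percent for 15 min, the cnb1 knockout with amiodarone for 30 min, and wild-type yeast with amiodarone for 1 h. Carvacrol is a phenolic compound of oregano oil with antifungal activity, and amiodarone is an antiarrhythmic drug that also acts on fungi. The amiodarone dose is not given in the sources used here.

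The deposited values were probe set signals on a linear intensity scale, with 1 column per array, and no column belonged to another series. Per the submitters' processing notes, MAS5 and PLIER were used. Which of them made the deposited intensity table, and with which version, is not given in the sources used here. The table held no zero, negative or missing value. The mean of each array without its highest and lowest 2 percent of values was 150.0 on all 5 arrays, so the arrays had been brought to a common scale before deposit. Such scaling holds the overall level of an array fixed, so a difference in total signal between samples cannot be read from that level. It could show only relative to the hybridisation controls added to each sample. Detection calls and scanner images were not used here.

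Gene names came from GEO's annotation of the platform, whose symbols were not updated further. One symbol was given for 41097 probe sets, several for 1801 and none for 11777. No gene was named from a probe set with several symbols. The names stand for the human sequence a probe set was designed on. The 62 Affymetrix control probe sets were described by kind and kept apart from the genes. Of these, the E. coli and phage P1 probe sets detect labelled RNA added just before hybridisation. The B. subtilis probe sets detect polyadenylated RNA that some protocols add before labelling. The human ones described detect actin, GAPDH, rRNA and the Alu repeat, and 1 further kind is not reported here.

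The signals were analysed as log2 of the intensity plus a pseudocount of 16, with no further scaling, so all log2 differences are on this scale and understate the change of dim probe sets. A probe set was called recurrently bright when it lay in the top 1 percent of every one of the 5 arrays. Agreement between arrays was measured by Pearson and Spearman correlation across probe sets, which are not independent replicates. Affymetrix ID classes and gene lists among the recurrently bright probe sets were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the classes or lists. Odds ratios for probe set groups have exact 95 percent confidence intervals. Of the 17 gene lists, 10 held genes with yeast homologs, 6 held vertebrate genes and 1 held mitochondrially encoded genes. The conserved lists were ribosomal proteins, core histones, actins and tubulins, translation factors, chaperones (mostly of the HSP70 and HSP90 families, with HSP60, HSP10 and HSP40 members), glycolysis, ubiquitin and proteasome, calcineurin with calmodulin and 14-3-3, small GTPases, and ATPases and ion pumps. The vertebrate lists were abundant human transcripts without a yeast homolog, keratins, blood and liver secreted proteins, olfactory and taste receptors, cytokines and chemokines, and C2H2 zinc fingers. Each list's median signal was also ranked among 10000 random draws of as many named probe sets.

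Treatment comparisons used the 5468 probe sets in the top 10 percent by mean log2 signal. With 1 array per group, pairs of arrays were compared by counts of probe sets differing 2-fold or more, with no test. A carvacrol slope was fitted with limma on 3 arrays, which left 1 residual degree of freedom. A factor for the drug (none, carvacrol or amiodarone) was fitted with limma on all 5 arrays, which left 2. The spread in that fit came from arrays that also differed in dose, genotype or time, and the lone untreated array was assumed to vary like the others. The threshold was an adjusted p of 0.05. Shifts of gene lists between arrays were ranked among 10000 random draws matched on mean signal in 20 bins. Correlations and shared names between comparisons that share the untreated array were set beside 100 draws in which each probe set's 5 values were reassigned among the arrays.

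The genes named were fixed by a rule. It took the 20 single-symbol genes with the highest minimum over the 5 arrays, the 2 brightest members of each list, and the brightest and dimmest control of each kind. For carvacrol and for amiodarone it took the 10 genes highest and the 10 lowest against untreated yeast, by the smaller of the differences on both arrays of the drug. For the knockout against the wild type it took 5 in each direction, besides both human genes of the calcineurin B subunit. Any other gene or probe set named was picked after its values were seen, which is said where it appears.

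The methods were tested on simulated data. In the count of recurrently bright probe sets, 299 of 300 planted among 54675 were found, with 0 false. In the amiodarone fit on 5468 probe sets, with a spread as between these arrays, 59 of 100 planted differences of 4 on the log2 scale and 98 of 100 of 8 were found, with 5 false calls. With a spread of 0.2, 83 of 100 differences of 1 and 100 of 100 of 2 were found, with 13 false calls. That spread is far below the median SD over these 5 arrays, 0.955 over all probe sets, so these shares do not apply here. At each spread both sizes were planted in the same data. The larger ones can ease the adjusted p of the smaller, whose share found may be lower in data without them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. The alternatives were median scaling, quantile normalization, scaling on the hybridisation controls, a pseudocount of 1, other filters and rank thresholds, leaving out the control probe sets, pooling the treated arrays, and leaving out each array. The number of arrays limits the precision of every value.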

Results

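Background on a human expression array was examined with RNA that held no human transcripts by design. Yeast RNA was hybridised to 5 arrays of 54675 probe sets, 1 for each of 5 conditions, so no condition had a replicate. The SD given with a mean is therefore the spread over 5 arrays that differ in treatment, n = 5. Median signal lay between 86.9 and 94.8 on the 5 arrays and the 99th percentile between 864.4 and 974.9. The range of the log2 medians was 0.11. Signal differs between probe sets for reasons of probe affinity as well as target, so levels of different probe sets are not compared as expression.

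The first question was which signals yeast RNA gave on the human control probe sets. The 18 E. coli and phage P1 hybridisation controls, whose labelled targets are added to the hybridisation mix, were in the top 1 percent of every array, with signals from 19400 to 755200. Human 28S ribosomal RNA, a conserved RNA, gave 9428 ± 2910 (SD, n = 5) on its 3' probe set AFFX-M27830_3_at, and 2 of its 3 probe sets were bright on every array. The dimmest, AFFX-M27830_M_at, gave 605.4 ± 395.8. The brightest 18S rRNA probe set, AFFX-HUMRGE/M10098_5_at, gave 1214 ± 580 and was not in the top 1 percent of all arrays, and the dimmest, AFFX-HUMRGE/M10098_M_at, gave 555.5 ± 146.3.

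The beta actin controls ranged from 207.3 ± 220.9 on AFFX-HSAC07/X00351_3_at to 822.9 ± 272.1 on AFFX-HSAC07/X00351_5_at. Those of GAPDH, a glycolytic enzyme, ranged from 213.8 ± 159.1 on AFFX-HUMGAPDH/M33197_M_at to 506.3 ± 124.4 on AFFX-HUMGAPDH/M33197_3_at. None of these 6 probe sets reached the top 1 percent of every array. The 27 B. subtilis controls lay between 3.755 and 791.4, and none was recurrently bright. The brightest was AFFX-r2-Bs-phe-3_at with 480.1 ± 196.8 and the dimmest AFFX-r2-Bs-dap-3_at with 16.38 ± 6.667. The Alu repeat control, AFFX-hum_alu_at, gave 880.8 ± 737.8. The hybridisation controls ran from AFFX-BioB-3_at with 22840 ± 2664 to AFFX-r2-P1-cre-3_at with 573500 ± 107600. Their geometric mean was 126146 on the untreated array, 103809 and 101032 at the lower and higher carvacrol dose, 90894 on the knockout array and 102117 on the wild-type amiodarone array. The untreated array thus stood 1.388 times above the lowest.

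**Figure D1:**
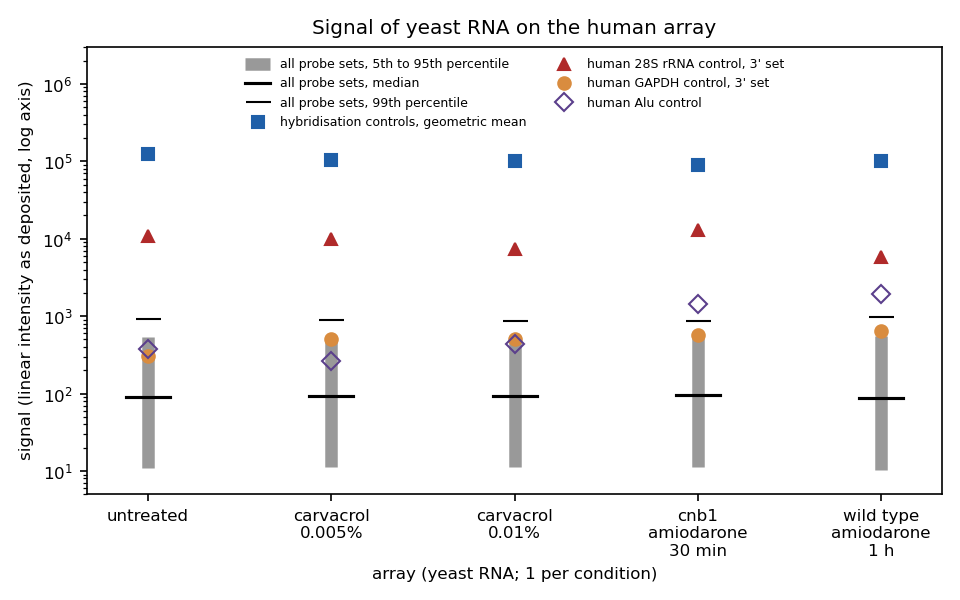
Signal on a log axis (linear intensity as deposited) for the 5 arrays on the horizontal axis, with the 5th to 95th percentile of all probe sets as a grey bar, their median and 99th percentile as lines, and controls as symbols. The geometric mean of the hybridisation controls lies at 90894 or above on every array, while the median of all probe sets lies at 94.8 or below.

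The second question was whether the background was a fixed property of a probe set. A small set of probe sets was bright on every array. It held 155 probe sets, of which 20 were Affymetrix controls and 135 were not. Each array had 547 probe sets in its top 1 percent, so 28.3 percent of an array's brightest probe sets were shared by all 5. Had the arrays ranked probe sets independently, 5.468e-06 would have been shared. Of the 1274 probe sets in the top 1 percent of any array, 626 (49.1 percent) were there on 1 array only. The 135 probe sets that were not controls had a median signal of 1625, and 19 of them stayed above 2000 on every array.

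Over all probe sets, the recurrently bright ones included, the background varied from array to array. Pearson's r of log2 signals was between 0.463 and 0.540 in the 10 pairs of arrays, with a median of 0.502. Spearman's rho was between 0.429 and 0.505, with a median of 0.468. The arrays shared 50.1 percent of the log2 variance over probe sets, and the median probe set differed 7.31-fold between its highest and lowest array. These correlations are across probe sets, which are not independent replicates. On the linear scale the median r was 0.998, and 0.729 without the Affymetrix controls, an alternative chosen after seeing the data.

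The 109 recurrently bright probe sets with a single gene symbol named 106 genes, led by PACS2, TMEM165, SFTPC, SLC22A25 and ARID1B. PACS2, a sorting protein of contacts between endoplasmic reticulum and mitochondria, gave 8551 ± 1174 (1555823_at). TMEM165, a Golgi membrane protein, gave 8805 ± 2283 (226825_s_at). SFTPC, the lung surfactant protein C, gave 6193 ± 1227 (38691_s_at). SLC22A25, a member of the organic anion transporter family, gave 7588 ± 4505 (1561093_at), with 13620 on the untreated array and 3745 on the knockout array. ARID1B, a subunit of the SWI/SNF chromatin remodelling complex, gave 5677 ± 2510 (1566990_x_at). IGHG1, an immunoglobulin heavy chain constant region, gave 4551 ± 1807 (217369_at), CD79A, a signalling chain of the B cell receptor, gave 3372 ± 882 (1555779_a_at), and LAIR1, an inhibitory receptor of leukocytes, gave 3124 ± 558 (210644_s_at).

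The steadiest of these 20 genes relative to its mean was GRK2, a kinase of G protein-coupled receptors, with 3120 ± 322 (38447_at). OTUB1, a deubiquitinase, gave 3892 ± 930 (38710_at), and WNT6, a secreted Wnt ligand, gave 2731 ± 432 (71933_at). The remaining ones were N4BP1, LMF1, IGSF3, DTX2P1-UPK3BP1-PMS2P11, ATP6AP1-DT, SPATA24, R3HDM4, RIPOR1 and LINC01210, with means from 2234 for LINC01210 to 3445 for DTX2P1-UPK3BP1-PMS2P11. Of the 20 genes, 19 had further probe sets, and only ARID1B and DTX2P1-UPK3BP1-PMS2P11 had another recurrently bright one. The median signal of the other probe sets was 45.33 for PACS2, 43.11 for TMEM165, 24.71 for WNT6 and at most 1120 for any of them. None of the 20 genes was in a list fixed before the data were examined. Of the recurrent probe sets with no single gene name in the table used, those with the highest minimum over the arrays were picked after their values were seen: 211606_at gave 25940 ± 8870, 56197_at gave 7816 ± 1690 and 238398_s_at gave 5900 ± 1760.

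**Figure D2:**
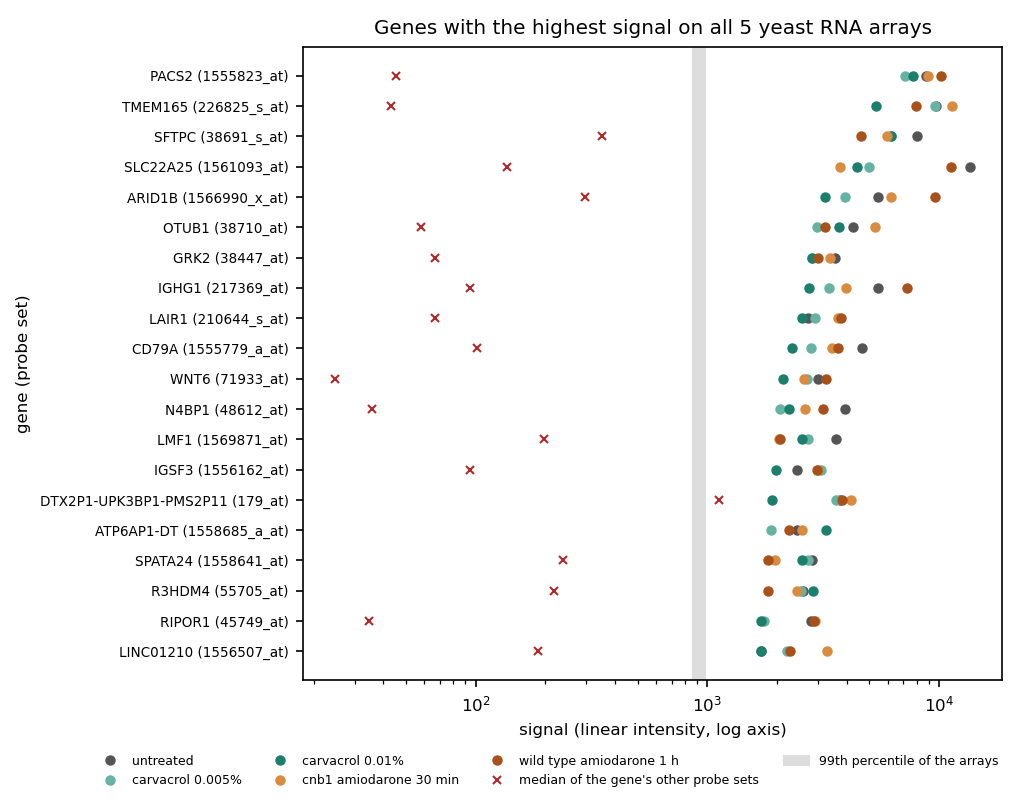
Signal (linear intensity, log axis) of the 20 genes with the highest minimum over the 5 arrays, 1 dot per array coloured by condition, with the median of each gene's other probe sets as a cross and the 99th percentiles of the arrays as a grey band. Every dot lies above 974.9, while all crosses but that of DTX2P1-UPK3BP1-PMS2P11, at 1120, lie below 864.4.

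The third question was whether the bright probe sets stood for genes conserved in yeast. Members of 7 of the 17 lists were recurrently bright, 1 or 2 probe sets in each. Among the conserved lists these were ACTC1, the cardiac actin (205132_at, 1794 ± 366), UBE2D4, a ubiquitin-conjugating enzyme (58900_at, 1486 ± 130), SFN, the 14-3-3 protein sigma (33322_i_at, 1606 ± 248), and RAB2A, a GTPase of vesicle transport (208730_x_at, 1363 ± 448). Among the vertebrate lists they were MT2A, a metallothionein (212185_x_at, 1454 ± 381), CCL22, a chemokine (207861_at, 1586 ± 352), and the zinc fingers ZNF135 (1567410_at, 2119 ± 514) and ZNF169 (1560921_at, 1851 ± 182). No list differed from the other named probe sets by Fisher's exact test, with a smallest adjusted p of 0.6787 over the 17 lists and 0 lists at an unadjusted p under 0.05. For the conserved lists together, 4 of 659 probe sets (0.607 percent) were recurrently bright against 0.2597 percent of the others, an odds ratio of 2.345 (95 percent interval 0.6255 to 6.214, exact p = 0.09868). For the vertebrate lists together it was 4 of 1403, with an odds ratio of 1.078 (0.2879 to 2.849, exact p = 0.7896).

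Most lists had no recurrently bright member. The ribosomal proteins named were RPL38 (202028_s_at, 651.8 ± 148.0) and RPS4X (213347_x_at, 627.1 ± 154.3). Of 121 ribosomal protein probe sets, 0 were recurrently bright, against 0.266 percent of the other named probe sets. At that share lists of such sizes hold few or no recurrently bright members, so an absence does not show depletion. The histones named were H3C6 (214616_at, 653.3 ± 179.7) and H4C8 (208180_s_at, 663.1 ± 151.8). TUBA1B, an alpha tubulin, gave 913.2 ± 141.2 (212639_x_at), the proteasome subunit PSMB6 511.3 ± 166.5 (208827_at), the 14-3-3 protein YWHAB 517.7 ± 188.9 (217717_s_at), and RAB7A, a late endosome GTPase, 1011 ± 267 (227602_at). Among translation factors EIF4E gave 494.0 ± 107.5 (242674_at) and EEF1A1 657.8 ± 276.6 (204892_x_at). The HSP70 chaperone HSPA6 gave 385.3 ± 49.4 (117_at) and HSPE1, a co-chaperonin, 299.5 ± 116.6 (205133_s_at). From the ATPase list, ATP5MC2 gave 821.2 ± 279.8 (207552_at) and ATP6V1H 595.3 ± 284.8 (1557586_s_at). The mitochondrially encoded ND2 gave 159.4 ± 59.4 (1553551_s_at) and COX2 100.7 ± 69.4 (1553569_at).

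CD63, a tetraspanin, gave 740.8 ± 172.0 (200663_at), and the keratins KRT7 and KRT2 gave 1337 ± 449 (1558393_at) and 898.4 ± 182.9 (207908_at). Beta globin, HBB, gave 673.2 ± 134.9 (211696_x_at), and the fibrinogen chain FGA gave 476.8 ± 148.8 (205650_s_at). The olfactory receptors OR10H3 and OR1I1 gave 795.0 ± 59.0 (208520_at) and 797.6 ± 251.5 (234403_at), and the cytokine IL16 gave 1053 ± 303 (1555016_at).

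Glycolysis differed at a wider threshold. With the top 5 percent of every array in place of the top 1 percent, 4 of 41 glycolysis probe sets (9.76 percent) were shared by all arrays against 1.06 percent of the other named probe sets, an odds ratio of 10.1 with an adjusted Fisher exact p of 0.0162. These were TPI1, triosephosphate isomerase (200822_x_at, 832.9 ± 174.1), ENO1, enolase (216554_s_at, 883.2 ± 149.2), and both probe sets of PFKL, a phosphofructokinase picked after its values were seen (201102_s_at, 777 ± 171, and 211065_x_at, 846 ± 203). The test counted the PFKL probe sets as separate members, and a test by gene was not run at the top 5 percent. Actins and tubulins had 3 of 40, with an odds ratio of 7.55 and an adjusted exact p of 0.0759. The rest of the list's 41 probe sets, other probe sets of TPI1 and ENO1 among them, did not reach this level on every array.

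By median signal, 0 lists lay in the highest 2.5 percent of random draws on all 5 arrays and 0 in the lowest. The 466 C2H2 zinc finger genes lay between the 0.0 and 5.2 percentile, with a list median of 76.79, and olfactory and taste receptors between the 89.2 and 99.6 percentile, with a median of 129.4. The conserved lists as a whole had a median of 91.58 against 92.34 for all named probe sets. Ribosomal proteins went from the 4.9 to the 84.2 percentile and translation factors from the 13.0 to the 98.3 percentile between arrays.

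Affymetrix marks probe sets whose probes are shared between transcripts by a letter in the ID. Among recurrently bright probe sets the shares of these classes did not differ by Fisher's exact test, with a smallest adjusted p of 0.1549 over 4 classes. The share was 0.4651 percent for _a_at, 0.3803 percent for _x_at, 0.2329 percent for plain _at and 0.186 percent for _s_at probe sets. At the top 5 percent, 3 classes differed from the rest, with odds ratios of 1.66 for _a_at (adjusted exact p = 0.018), 1.59 for _x_at (adjusted exact p = 0.0038) and 0.699 for _s_at (adjusted exact p = 0.00421).

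Carvacrol was compared with untreated yeast at both doses. Ranked by the smaller of the differences at both doses, probe sets of GAU1, SPRING1 and UPF1 stood highest above the untreated array. GAU1 (1559538_at) went from 34.64 untreated to 774.7 at 0.005 percent and 681.3 at 0.01 percent, log2 differences of 3.96 and 3.78. SPRING1, a regulator of the sterol response (218867_s_at), differed by 4.20 and 3.77, and UPF1, the helicase of nonsense-mediated mRNA decay (211168_s_at), by 3.70 and 4.07. By the same measure, the lowest were LINC00452 (1570447_at), from 1153 to 110.8 and 64.52, log2 differences of -3.20 and -3.86, and LOC728743 (225907_at), with -2.72 and -2.94.

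The other probe sets named higher at both doses were those of ERBB3, a receptor tyrosine kinase (1563253_s_at, 3.67 and 3.71), REEP2 (205331_s_at, 3.60 and 3.89), BRF2, a transcription factor of RNA polymerase III (218955_at, 3.55 and 3.71), ITPK1, an inositol phosphate kinase (210740_s_at, 3.89 and 3.39), the potassium channel KCNQ3 (206573_at, 3.41 and 3.38), TMEM145 (1553479_at, 3.26 and 3.39) and the protocadherin PCDH7 (210273_at, 3.99 and 3.26). Those named lower were CYB561D1 (227981_at, -2.78 and -2.44), POMT2 (225560_at, -2.47 and -2.12), SLC6A17 (233287_at, -2.09 and -2.28), JMJD8 (224886_at, -2.54 and -2.05), the erythropoietin receptor EPOR (396_f_at, -2.13 and -1.85), the histone variant H2AX (212525_s_at, -1.80 and -2.22), MLX (217910_x_at, -2.47 and -1.79) and RANGAP1 (1553535_a_at, -1.72 and -2.17). All 10 probe sets named higher had an untreated signal of at most 73.15, below that array's median of 89.15, so the size and order of these differences depend on the pseudocount. With a pseudocount of 1, UPF1 differed by 4.48 and 4.86, SPRING1 by 4.85 and 4.41, and GAU1 by 4.44 and 4.26. The genes' other probe sets differed far less. Of 35 such probe sets of 14 genes, 22 went the same way, with a median of 0.17 against 3.36 for the named ones. The named ones were picked for large differences and the others were not, so a gap is given by the rule.

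At 0.005 percent, 746 of the 5468 brighter probe sets were at least 2-fold above the untreated array and 661 below, and at 0.01 percent 732 were above and 766 below. Between the doses, 571 were higher and 679 lower at 0.01 percent. The 10 pairs of arrays all had between 1142 and 1498 such probe sets. With scaling on the hybridisation controls, an alternative chosen after seeing the data, the splits became 1102 above and 433 below at 0.005 percent and 1098 above and 462 below at 0.01 percent, and the median log2 difference of all probe sets was 0.22 and 0.24 after this scaling. The limma slope on carvacrol called 0 of 5468 probe sets, with 357 at an unadjusted p under 0.05, a smallest adjusted p of 0.728 and a median SE of 0.73 on the log2 scale per 0.01 percent. For UPF1 (211168_s_at) the slope was 4.07 ± 1.06 (SE) and for LINC00452 (1570447_at) it was -3.86 ± 0.92, and limma called neither. With evenly spaced doses the slope equals the difference at 0.01 percent, and a departure of the lower dose from the line counts as error. A difference already as large at 0.005 percent thus raises the SE. With both carvacrol arrays as one group in the limma fit on all 5 arrays, 0 were called as well, with 441 at an unadjusted p under 0.05, of which 348 were higher, and a smallest adjusted p of 0.19.

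**Figure D3:**
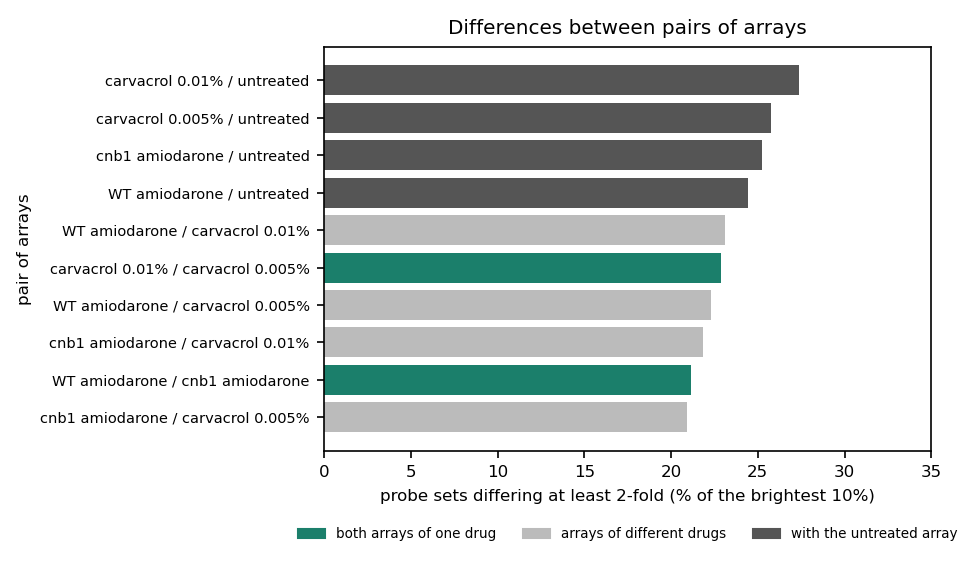
Percent of the 5468 brighter probe sets (horizontal axis) that differed at least 2-fold in each of the 10 pairs of arrays (vertical axis), with bars from 0. The pairs with the untreated array lie between 24.43 and 27.4 percent and the others between 20.89 and 23.12 percent, and the 2 pairs of arrays of one drug, in green, fall among those of different drugs.

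Amiodarone was compared with untreated yeast on the wild-type and knockout arrays. Per its title the untreated array was the control for carvacrol, and no control for amiodarone is given. These differences may therefore hold differences between experiments, which could not be told apart from the drug. By the smaller of the differences on both arrays, UPF1 and SPRING1 stood highest above the untreated array. All 10 probe sets named higher had an untreated signal of at most 63.33, below that array's median, so the size and order of their differences depend on the pseudocount. UPF1 (211168_s_at) went from 18.37 untreated to 573.3 in the wild type and 807.3 in the knockout, log2 differences of 4.10 and 4.58, and SPRING1 (218867_s_at) differed by 3.95 and 4.22. The T cell receptor constant region TRBC1 (210915_x_at) differed by 3.75 and 4.03. With a pseudocount of 1, UPF1 differed by 4.89 and 5.38. Lowest by that measure was GRK6, a receptor kinase (210981_s_at), from 1364 to 175.3 and 134.6, with -2.85 and -3.20.

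The other probe sets named higher were those of PCDH7 (210273_at, 4.15 and 3.74), MLLT6 (225628_s_at, 3.71 and 4.13), HABP4 (232341_x_at, 4.17 and 3.59), NLRX1, a mitochondrial innate immune receptor (1553695_a_at, 3.53 and 3.45), LINC02981 (240194_at, 3.46 and 3.42), KY (1564254_at, 3.72 and 3.38) and BRF2 (218955_at, 3.30 and 3.40). Named lower were the transcription factor TBX3 (225544_at, -2.83 and -2.26), SPRR2G (236119_s_at, -2.78 and -2.23), the histone methyltransferase SUV39H1 (218619_s_at, -2.23 and -3.28), TATDN2 (203648_at, -2.64 and -2.16), MYOZ3 (1562004_x_at, -2.09 and -2.63), LZTS2 (1555881_s_at, -2.88 and -2.01), TBC1D13 (44696_at, -1.98 and -2.47), the elongation factor TCEA1 (1566207_at, -1.97 and -3.22) and FIZ1 (226967_at, -2.37 and -1.93). Of 45 other probe sets of 18 of these genes, 22 went the same way, with a median of -0.04 against 3.19 for the named ones. Here too the rule picked only the named ones for large differences.

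The limma fit called 0 of 5468 probe sets between the amiodarone arrays and the untreated one, with 453 at an unadjusted p under 0.05, of which 380 were higher, and a smallest adjusted p of 0.209. The median SE was 0.62 on the log2 scale. For UPF1 (211168_s_at) the difference was 4.34 ± 0.57 (SE) and for SPRING1 (218867_s_at) 4.08 ± 0.56, and limma called neither. The naming rule had picked both for being higher on both arrays. With all 4 treated arrays as one group, an alternative chosen after seeing the data, limma called 0 as well, with a smallest adjusted p of 0.0755. Without the filter on mean signal, 2032 of 3986 probe sets at an unadjusted p under 0.05 by limma were higher. At least 2-fold differences numbered 808 above and 528 below for the wild type, and 743 above and 636 below for the knockout. For the wild type the split became 1246 above and 344 below with scaling on the hybridisation controls, after which the median log2 difference of all probe sets was 0.22.

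Both sets of differences used the same untreated array, and the overlap of the named probe sets lay within what this alone gave. UPF1, SPRING1, PCDH7 and BRF2 were named for both. Of the 20 probe sets named for carvacrol, 16 had the same sign on both amiodarone arrays, and of the 20 named for amiodarone, 17 had it on both carvacrol arrays. With the naming rule run on values reassigned among arrays, the medians over 100 draws were 17 and 16 of 20, and 4 shared names, with at least as many as observed in 78, 46 and 68 draws. Over 5468 probe sets, the differences from the untreated array correlated with r = 0.58 between the carvacrol doses, 0.59 between the amiodarone arrays, and 0.56 between carvacrol at 0.01 percent and wild-type amiodarone. With values reassigned in this way, so that only the shared array linked the differences, r was 0.50, and at most 0.53 in any of 100 draws. The covariances were 0.62, 0.59 and 0.58, against 0.47 without an effect and at most 0.52 in any draw. The pair of unlike drugs thus came close to the pairs of one drug. Reassignment let the untreated array vary only as much as the others. Part or all of the excess may therefore come from that shared array, which could not be split. That array also stood farthest from the rest, with an SD of 0.84 against the mean of the others, while the treated arrays had 0.72 to 0.76.

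The knockout was compared with the wild type under amiodarone, where genotype and treatment time (30 min against 1 h) differed together. The human genes of the calcineurin B subunit, the homologs of the deleted yeast gene, cannot check the deletion, since human probes were not designed on the yeast transcript. PPP3R1 gave 439.3 in the knockout and 252.0 in the wild type on 204506_at, and 5.731 and 32.77 on 204507_s_at. PPP3R2 gave 41.63 and 64.60 on 231304_at, and 6.203 and 8.311 on 244782_at. The untreated array had 370.3 and 20.03 for PPP3R1, and 41.83 and 15.16 for PPP3R2.

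Probe sets named higher in the knockout were those of LCN8 (239369_at, 726.9 against 49.8, a log2 difference of 3.50), YLPM1 (214713_at, 3.45), RNF217 (235492_at, 3.28), the calcium channel CACNA1I (221631_at, 3.26) and ZNF428 (215429_s_at, 3.23). Named lower were MROH2B (240412_s_at, 82.09 against 1680, a log2 difference of -4.11), AGGF1 (208042_at, -4.06), the clathrin adaptor subunit AP2A1 (223237_x_at, -3.95), the translesion polymerase REV1 (222628_s_at, -3.94) and RDM1 (239169_at, -3.93). The lower signal of each pair lay below its array's median, so the size and order of these differences depend on the pseudocount. With a pseudocount of 1, YLPM1 differed by 3.88 and LCN8 by 3.84, and AGGF1 by -4.54 and MROH2B by -4.34. Against the untreated array, the knockout and the wild type differed by -0.22 and -3.66 on YLPM1, 0.17 and -3.11 on RNF217, 0.74 and -2.52 on CACNA1I, and 1.04 and -2.46 on LCN8, so the low wild-type signal made most of these 4 differences. On ZNF428, with 1.85 and -1.37, it did not. Of those named lower, they differed by -2.89 and 1.22 on MROH2B, -3.18 and 0.88 on AGGF1, -3.38 and 0.57 on AP2A1, -2.81 and 1.13 on REV1, and -1.26 and 2.67 on RDM1. Of 5468 probe sets, 489 were at least 2-fold higher and 666 lower in the knockout. This comparison had no residual degree of freedom and no test. With scaling on the hybridisation controls the split turned to 644 higher and 500 lower, and the median log2 difference of all probe sets was then 0.14.

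Few gene lists stood apart between arrays. Over the 17 lists and 5 comparisons, 5 of 85 medians lay outside 95 percent of random draws matched on signal, where 4.25 would by chance. Translation factors had a median log2 difference of 0.63 at 0.005 percent carvacrol, with 15 of 47 probe sets at least 2-fold above and 6 below. Small GTPases had -0.57 in the wild type with amiodarone, with 13 of 79 above and 27 below. The ATPases and ion pumps had 0.33 in the knockout against untreated, the abundant human transcripts 0.40 at 0.01 percent carvacrol, and the blood and liver proteins -0.52 at 0.005 percent carvacrol. None of the 17 lists lay outside that range for the knockout against the wild type.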

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

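Of 65 alternative values of the main results, 49 stayed within the range set for an unchanged value and 16 moved. Some splits into higher and lower changed sides. For 0.01 percent carvacrol, 732 above and 766 below became 801 and 705 with quantile normalization and 1098 and 462 with scaling on the hybridisation controls. For the knockout against the wild type, 489 above and 666 below became 644 and 500 with the latter. The recurrently bright probe sets numbered 97 with the top 0.5 percent, 572 with the top 5 percent and 33 above the median plus 3 left-sided SDs, as a stricter or wider threshold must give. Leaving out each array in turn gave 167 to 184 recurrently bright probe sets, more because 4 arrays had to share them. It gave a median r between arrays of 0.487 to 0.514. That r was 0.473 in the top 10 percent. It was 0.998 on the linear scale but 0.729 there without the controls, so the very bright controls made much of the 0.998. Why the linear r without controls still lay above the log2 one was not tested. Leaving out each of the 4 treated arrays gave 0 limma calls for amiodarone. At the top 5 percent, 3 probe set classes and 1 gene list passed. Counts of 2-fold differences were larger with more probe sets compared, and so was their share, which without a filter went from 27.4 to 45.4 percent for 0.01 percent carvacrol and from 21.1 to 41.7 percent for the knockout against the wild type. Without a filter they were 24845 for 0.01 percent carvacrol, 24646 for 0.005 percent, 23915 for wild-type amiodarone and 22785 for the knockout against the wild type, and with the top 25 percent 5188, 5087, 4928 and 4409. Without a filter, 11906 were above and 12009 below for wild-type amiodarone, and 11922 above and 10863 below for the knockout. The filter on the mean keeps probe sets that are low on 1 array alone, so it can tilt such splits. No limma fit called a probe set under the other scalings, pseudocount or filters run. The 90 named log2 differences kept their sign under the other scalings and pseudocount. They moved by at most 0.80 with a pseudocount of 1, 0.46 with scaling on the hybridisation controls, 0.13 with quantile normalization and 0.11 with median scaling. The alternatives on the hybridisation controls, without controls and with the treated arrays pooled were chosen after seeing the data. No paired analysis was possible because each group had 1 array. No detection calls were used, so no single probe set was tested for signal over background.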

Other observations

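Alu repeat signal separated the amiodarone arrays from the others. The control AFFX-hum_alu_at gave 1423 in the knockout and 1905 in the wild type with amiodarone, against 374 untreated, 262 at 0.005 percent and 440 at 0.01 percent carvacrol, so the lower amiodarone array stood 3.23 times above the highest of the rest. With quantile normalization the ratio was 3.38 and with scaling on the hybridisation controls 3.60. This probe set was picked after its values were seen. The 3' beta actin control, AFFX-HSAC07/X00351_3_at, looked at likewise, gave 548 in the knockout and 316 in the wild type with amiodarone, against 53 to 67 on the rest. The middle one, AFFX-HSAC07/X00351_M_at, gave 419 and 366 against 76 to 253. The 5' one, AFFX-HSAC07/X00351_5_at, did not separate these arrays, with 1048 and 440 against 637 to 1042. The cause was not tested. Of all 54675 probe sets, 804 had both amiodarone arrays at least 2-fold above the other 3, and over the 10 ways to choose 2 arrays this count ran from 718 to 926. Of the unnamed probe sets, 211606_at gave 30169 and 39372 on the amiodarone arrays against 17566 to 22594 on the rest.

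Of the tests that follow, those on the shift of the higher number range, on human transcripts, carry-over and conserved transcripts, and on chance pairing were chosen after the result was seen. How large a lead would decide the scaling test was also judged after its counts were seen. The patterns themselves were found in these data, and no biological explanation was tested for the first.

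Recurrently bright probe sets concentrated in 2 ranges of probe set numbers, ranges set after the list of bright probe sets was seen. Below 200000, 26 of 493 (5.274 percent) were recurrently bright, and above 1000000, 65 of 9921 (0.6552 percent). Between them it was 44 of 44199 (0.09955 percent). Against all other probe sets that were not controls, the odds ratios were 27.58 (95 percent interval 17.08 to 43.09) and 4.204 (2.95 to 5.983). Probes shared by design, as marked by the ID letter, would leave no excess among plain _at probe sets. Yet the odds ratios there were 30.9 (17.9 to 51.3) and 5.13 (3.29 to 8.03). The letter cannot show shared probes that it does not mark or matches to yeast sequence, so this test does not exclude those. Below 200000 the range was brighter as a whole, with a median of 177.1 against 90.76, but raising the middle range by this difference gave 0.903 percent where 5.27 (3.47 to 7.63) was observed, so a uniform shift accounts for part at most, and above 1000000 the median log2 signal differed from the middle range by -0.019 (95 percent bootstrap interval -0.063 to 0.024) where a shift of 0.60 would be needed. A difference in how the probes of these ranges were designed may remain as an explanation and was not tested, since probe sequences were not used here.

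Probe sets of human genes stayed in the top 1 percent without human RNA. Human transcripts of the same genes are argued against, because the 241 other probe sets of 89 of these genes had 0.985 times (95 percent bootstrap interval 0.836 to 1.22) the median signal of all named probe sets, below the 3 times set as the bound. Carry-over of human RNA is argued against by the same bound, since abundant human transcripts reached at most 1.62 times that median (1.11 to 2.12), on the array with 0.01 percent carvacrol, and 0.783 times on the lowest. A trace too small to raise these medians 3 times would not be seen. Conserved yeast transcripts stay open as a partial source, with an odds ratio of 2.35 (0.625 to 6.21) for the conserved lists.

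Pairing the arrays by drug led the other pairings only narrowly in the 135 recurrently bright probe sets. This pattern was picked after the counts of all 10 pairs and several groups of probe sets had been looked at. It was weighed in place of the distance of the untreated array. Leaving out 1 array and pairing the other 4 can be done in 15 ways, and the drug pairing separated 71 probe sets against 68 for the highest other, 1 of 15 with as many, a share of 0.067, and 15 ways are too few for a share under 0.05. After quantile normalization the drug pairing had 63 against 62. With scaling on the hybridisation controls it had 71 against 83 and ranked 3 of 15. The lead was thus lost under 1 scaling, and scaling between arrays stays open. A drug response over all bright probe sets was predicted to rank the drug pairing 1 of 15 in the other 5302 probe sets of the top 10 percent. It ranked 12, with 2068 separated in a range of 2036 to 2225. A range this narrow cannot exclude a response in a small part of them. In the top 10 percent the amiodarone arrays had the highest r of the 10 pairs, 0.51, while the carvacrol arrays, with 0.475, lay among the other pairs. This question stays open. A drug effect limited to the recurrently bright probe sets stays possible and was not tested further.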
